A study of Homo sapiens with 2 samples.

How the data were processed

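Small RNA was sequenced from exosomes, the small vesicles that cells release, collected from the medium of 2 human liver cancer cell lines. MHCC97H is a hepatocellular carcinoma line with high metastatic potential. HepG2 is a liver cancer line that the labels also call hepatocellular carcinoma. There was 1 library per cell line. Per the labels' protocols and design text, cells grew in medium with serum depleted of exosomes, and vesicles were pelleted by ultracentrifugation. RNA was taken up in TRIzol, and size-selected libraries were made with an NEBNext small RNA kit and read on an Illumina NextSeq 500. The kit as described carries no molecular identifiers, so reads are not independent molecules.

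The authors deposited raw read counts per mature miRNA, 1 column per library, per the file headers. The submitters' processing notes name cutadapt and Bowtie. Their versions, the mismatch setting, the miRBase release and the genome build are not given in the sources used here. The table has 915 entries for 793 distinct mature miRNAs. It repeats 78 names, and for 30 of these the repeated counts were not equal. The repeats were read as 1 entry per hairpin copy of the same mature sequence, so the highest count of a name was used once. This choice was made after the table was seen, and the sum of the repeats was run as an alternative. miR-199a-3p and miR-199b-3p carry equal counts in both libraries, as do miR-365a-3p and miR-365b-3p, and reads of such pairs cannot be assigned to either name.

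After this step the MHCC97H library held 304457 miRNA reads and the HepG2 library 22831, a 13.3-fold difference in depth. One read is worth 3.28 CPM (miRNA counts scaled to a common library total) in MHCC97H and 43.8 CPM in HepG2. A count of 0 allows up to 3 reads, which is 9.85 CPM in MHCC97H and 131 CPM in HepG2. Total reads before mapping were not used here, so all values are relative to miRNA reads.

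CPM was computed from these totals. The log2 ratio of MHCC97H over HepG2 used a pseudocount of 1 CPM, among miRNAs with at least 10 CPM in at least 1 library. A difference was called by size, at 2-fold or more. Because 1 read in HepG2 already exceeds 10 CPM, that filter removes nothing detected in HepG2. A second criterion was therefore added after the depths were seen: the 95% interval of the ratio had to exclude 1. It is an exact Clopper-Pearson interval on the split of a miRNA's reads between the libraries. Folds in the text are plain CPM ratios with this interval. Against a count of 0, "at least" folds set the other library's CPM over the CPM of 3 reads. They take the other count as read, so they lie above the lower end of the exact interval, which is printed beside them or as a range. All intervals and floors cover counting error only. With 1 library per cell line there is no replicate check and no test between cell lines, and cell line and library preparation cannot be told apart.

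The procedure was tested on simulated data, with 793 miRNAs drawn at the real depths. In 100 draws with no change, the size rule alone called a median of 124.5 miRNAs for MHCC97H and 69 for HepG2. With the interval added, the medians were 1 and 4.5. In 20 draws with 200 changed miRNAs each, both criteria together recovered 50.6% of 2-fold, 96.0% of 4-fold and 100% of 8-fold changes at a mean of 500 CPM or more. Below that level they recovered 6.63%, 17.8% and 28.5%.

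27 lists of miRNAs (families, clusters, tissue and cell type markers, disease lists) were fixed before the data were examined. A mature miRNA belonged to a list when its name without arm and copy number matched. The median log2 ratio of each list with at least 3 members was placed among 10000 random lists matched on deciles of mean expression. Medians were also computed with zero counts set to 3 reads. There, a miRNA with no HepG2 read and fewer CPM in MHCC97H than the HepG2 floor falls on the HepG2 side by construction, so those medians are bounds and their sign gives no direction. Named miRNAs were the 10 most abundant of each library, the 8 largest log2 ratios with the 1 CPM pseudocount in each direction at 100 CPM or more, and up to 4 most abundant members of each list. Members named outside this rule, in the text on the miR-200, liver, 14q32, vesicle, mesenchymal and arm results, were chosen after their values were seen. Alternatives changed the scaling (edgeR's trimmed mean of M-values, median centring, a total without the most abundant miRNAs), the pseudocount, the filter, the fold and the counting of arms. All 104 named miRNAs were matched by symbol to hairpin genes of GENCODE release 29 (GRCh38). These coordinates place the hairpins and were not used in counting. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.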

Results

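The data were miRNA read counts from exosomes of MHCC97H and HepG2 cells, with 1 library for each line. The comparison asks how the miRNA content of exosomes differs between these 2 tumor cell lines. The MHCC97H library held 304457 miRNA reads and detected 763 of the 793 listed miRNAs. The HepG2 library held 22831 reads and detected 362. Of these, 157 had only 1 or 2 reads in HepG2, and 120 had 10 or more. Ratios that rest on few HepG2 reads are therefore imprecise.

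Both libraries were led by miR-21-5p, a miRNA raised in many tumors. It made up 14.4% of reads in MHCC97H (95% exact interval 14.3 to 14.6%) and 30.0% in HepG2 (29.4 to 30.6%). After it, the HepG2 library held miR-148a-3p, which is abundant in liver, at 142438 CPM and miR-1246 at 99558 CPM. Then came miR-6750-5p at 31405, miR-143-3p at 20849, miR-451a at 20104 and miR-27b-3p at 18878 CPM. miR-378a-3p (17038 CPM), miR-25-3p (16031 CPM) and miR-151a-3p (13841 CPM) completed its 10 most abundant. In MHCC97H the next were let-7f-5p at 53515, miR-151a-3p at 44936, miR-100-5p at 41671, miR-27a-5p at 39083 and let-7a-5p at 36678 CPM. let-7i-5p (27071 CPM), miR-27b-3p (27009 CPM), miR-148a-3p (26976 CPM) and miR-30a-5p (26917 CPM) followed. The lists shared 4 miRNAs. The 10 most abundant took 46.8% of MHCC97H reads (46.6 to 47.0%) and 68.0% of HepG2 reads (67.4 to 68.6%). The hairpin of miR-21 lies on chromosome 17 (59841266 to 59841337, plus strand, GRCh38), where it overlaps an exon of a VMP1 transcript. That of miR-148a lies on chromosome 7 (25949919 to 25949986, minus strand), outside any same-strand gene.

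MHCC97H exosomes carried more let-7 miRNAs, more of the miR-27a/24 and miR-30 groups, and more miR-100 and miR-99a. HepG2 exosomes carried more miR-148a-3p, miR-192-5p, miR-194-5p, miR-146a-5p and miR-483-5p. Of 543 miRNAs at 10 CPM or more in at least 1 library, 281 were at least 2-fold higher in MHCC97H and 137 were at least 2-fold higher in HepG2. Simulated libraries with no change gave medians of 124.5 and 69 at these depths. Of the 281, 181 had no HepG2 read, and 83 of the 137 rested on 1 or 2 HepG2 reads. With a counting interval that also excluded 1, 111 were higher in MHCC97H and 49 in HepG2, against simulated medians of 1 and 4.5. Among the 137 miRNAs averaging 500 CPM or more, 68 were higher in MHCC97H, 25 in HepG2, and 44 did not meet both criteria.

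The split between directions depended on scaling. The median log2 ratio of the 543 miRNAs was 1.12, and that of the 137 well covered ones was 0.99. Of all calls by size, 67.2% were for MHCC97H with library totals, 52.7% with median centring and 58.9% with a total that left out the most abundant miRNAs. Across the 543 miRNAs, Pearson's r of log2(CPM + 1) was 0.50 and Spearman's rho was 0.55. With median centring, MHCC97H ratios of log2 under 1.12 turn direction, among them those of miR-486-5p, miR-1260a, miR-27b-3p and miR-106b-3p. The r and rho are across miRNAs, which are not independent replicates.

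**Figure D1:**
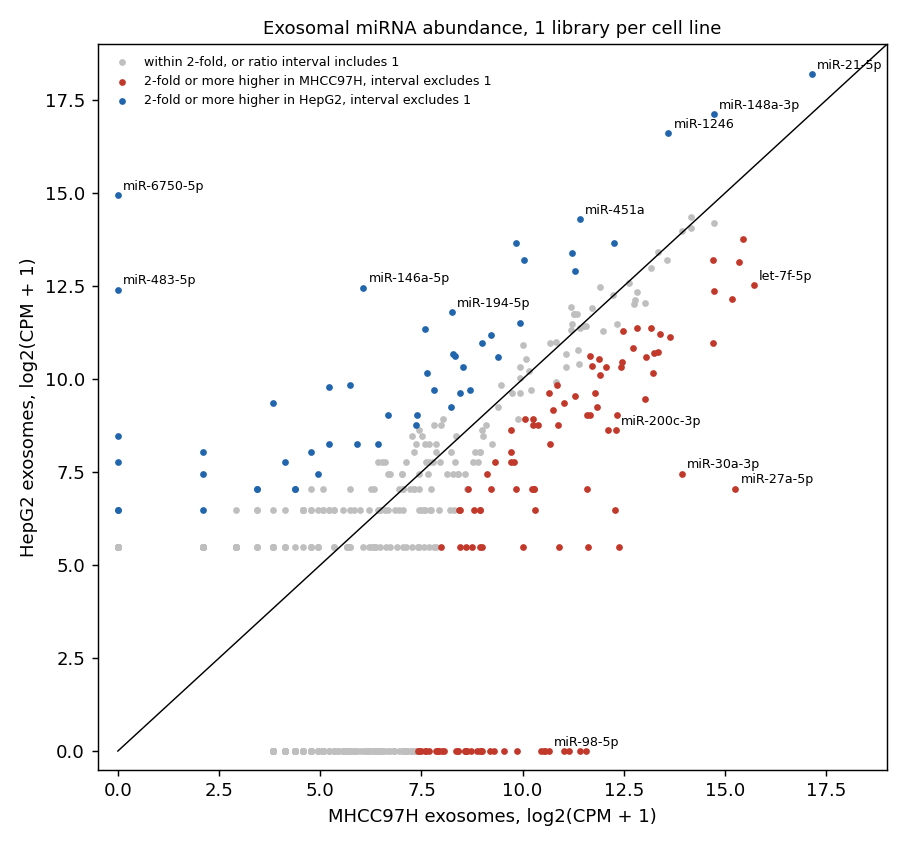
Abundance of the 543 miRNAs in MHCC97H exosomes (x axis) and HepG2 exosomes (y axis), both as log2(CPM + 1), 1 point per miRNA; the line marks equal abundance. The 111 red points and 49 blue points met both criteria for MHCC97H and HepG2, and the rows of points at the bottom are miRNAs with 0, 1 or 2 HepG2 reads.

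The let-7 family, miRNAs that restrain growth and RAS signaling, was the list with the clearest shift. Of 19 members at 10 CPM or more, 16 were higher in MHCC97H by both criteria, none in HepG2, and 3 met only the size criterion. let-7f-5p was 9.12-fold higher (95% interval 7.69 to 10.9), with 16293 reads against 134. let-7a-5p was 8.05-fold higher (6.64 to 9.86), let-7i-5p 5.11-fold (4.27 to 6.16) and let-7g-5p 2.85-fold (2.49 to 3.28). miR-98-5p, a family member in an intron of HUWE1 on chromosome X (53556223 to 53556341), had 487 reads against 0 and was at least 12.2-fold higher (exact lower end 9.86). The list's median log2 ratio was 4.37, and 2.55 with zero counts set to 3 reads. Both lay at or above the 99.99th percentile of matched random lists. The 4.37 is the value of let-7g-3p, with 6 reads against 0, so its size rests on the pseudocount. Among the 12 members averaging 500 CPM or more the median was 3.09.

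In the miR-23/27/24 clusters, 5 of 11 members were higher in MHCC97H by both criteria and none in HepG2. miR-23b-3p leaned to HepG2 (3942 CPM against 2348 in MHCC97H), under the size criterion. miR-27a-5p had 11899 reads against 3, a 297-fold difference (102 to 1442). miR-24-3p was 6.06-fold (4.42 to 8.54) and miR-27a-3p 5.84-fold higher (4.24 to 8.26). The MIR27A hairpin (chromosome 19, 13836440 to 13836517, minus strand) and MIR24-2 (13836287 to 13836359) lie next to each other, each overlapping an exon of an AC020916.1 transcript. miR-27b-3p, from the other cluster on chromosome 9, differed by 1.43-fold (1.30 to 1.58), under the size criterion. Its partner arm miR-27b-5p had 685 reads against 0. miR-23a-3p was called in neither direction (6848 CPM in MHCC97H, 4161 in HepG2). miR-24-3p has a hairpin in each place, MIR24-1 on chromosome 9 and MIR24-2 on chromosome 19. The calls thus did not divide fully by cluster, since miR-27b-5p was called and miR-23a-3p was not. The ratios did lean further to MHCC97H for miR-23a-3p and miR-27a-3p than for miR-23b-3p and miR-27b-3p. The same held for miR-24-2-5p (830 reads against 0) over miR-24-1-5p (25 against 1), on few HepG2 reads. miR-23a-5p, miR-23b-5p and miR-27b-5p had no HepG2 read, so their ratios could not be ordered. The list's median log2 ratio was 2.60, at the 99.3rd percentile, and 0.89 with zeros at 3 reads, at the 96.2nd.

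In the miR-30 family, 7 of 11 members were higher in MHCC97H and none in HepG2. These were miR-30a-5p, miR-30d-5p and the 3p arms miR-30a-3p, miR-30b-3p, miR-30c-2-3p, miR-30d-3p and miR-30e-3p. The other 5p arms were called in neither direction. In CPM of MHCC97H against HepG2 they were miR-30b-5p (1087 against 1489), miR-30c-5p (2910 against 2759) and miR-30e-5p (1803 against 2059). miR-30a-5p was 13.4-fold (10.0 to 18.3), miR-30e-3p 4.01-fold (2.83 to 5.88) and miR-30d-5p 3.53-fold higher (2.74 to 4.64). miR-30a-3p had 4770 reads against 4 and was 89.4-fold higher (34.9 to 328). The family's median log2 ratio of 2.32 lay at the 98.6th percentile. The 2.32 is the value of miR-30c-1-3p, with 68 reads against 1, which did not pass the counting criterion. With zeros at 3 reads the median was 1.82, at the 98.0th percentile, and among the 8 members averaging 500 CPM or more it was 1.91. The random lists were matched on expression and not on arm, so a difference between arms can enter these percentiles. In the miR-99/100 and miR-125 group, 9 of 11 members were higher in MHCC97H. miR-99a-5p was 5.76-fold (4.37 to 7.74), miR-100-5p 4.60-fold (4.01 to 5.30), miR-99b-5p 4.32-fold (3.00 to 6.47) and miR-125b-5p 3.01-fold higher (1.74 to 5.68). The median of 2.20 lay at the 96.6th percentile, and at the 99.2nd with zeros at 3 reads. MIR100 and MIR125B1 lie in introns of MIR100HG on chromosome 11 (MIR100 at 122152229 to 122152308, minus strand). miR-125b-5p also has a hairpin on chromosome 21, MIR125B2, and its reads cannot be assigned to either place.

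Of the miRNAs reported as raised in hepatocellular carcinoma, 11 of 24 were higher in MHCC97H, 3 in HepG2 and 10 did not meet both criteria. The cluster of miR-182, miR-96 and miR-183 had 3 of 6 members higher in MHCC97H, namely miR-182-5p (8.42-fold, 5.73 to 12.9), miR-96-5p (5.35-fold, 2.58 to 13.4) and miR-183-5p (3.53-fold, 2.38 to 5.47). Its median log2 ratio was 3.45, at the 83.9th percentile, and 0.05 with zeros at 3 reads, at the 98.1 percentile. The 3.45 rests in part on 3p arms with no HepG2 read. The pair miR-221 and miR-222, which represses the cell cycle inhibitor p27, had 3 of 4 members higher in MHCC97H, among them miR-222-3p (5.93-fold, 3.52 to 10.9) and miR-221-3p (2.28-fold, 1.75 to 3.02). Its median was 2.25, at the 96.7th percentile. miR-452-5p (6.17-fold, 3.52 to 11.99) and miR-224-5p (4.45-fold, 2.80 to 7.54), whose hairpins each overlap an exon of a GABRE transcript on chromosome X, were higher in MHCC97H. The median of this pair's 3 entries was 2.62, at the 77.4th percentile. The hypoxia-induced miR-210-3p was 3.17-fold higher (1.21 to 11.8) on 4 HepG2 reads. miR-21-5p went the other way and was 2.08-fold higher in HepG2 (2.03 to 2.13), while its partner arm miR-21-3p was 5.56-fold higher in MHCC97H (3.99 to 8.01). miR-493-5p and miR-493-3p were the other 2 higher in HepG2. The list's median was 1.88, at the 98.0th percentile. The list reported as reduced in this cancer had 6 of 25 members higher in MHCC97H and 3 in HepG2. Its median was 0.38 at the 24.9th percentile, and was negative under 5 alternatives that leave zero counts as they are, 3 of them other scalings. The HepG2-side members were miR-29c-3p, miR-145-5p and miR-199b-5p, and miR-26a-5p differed by 1.30-fold (1.13 to 1.502).

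HepG2 exosomes carried more of several liver-enriched miRNAs. Of 10 members of that list, 5 were higher in HepG2, 1 (miR-148a-5p, 3.03-fold, 1.63 to 6.37) in MHCC97H and 4 did not meet both criteria. miR-148a-3p was 5.28-fold higher in HepG2 (5.07 to 5.50), at 3252 reads against 8213 in the deeper library. miR-192-5p was 4.48-fold (3.86 to 5.18) and miR-194-5p 11.7-fold higher (8.60 to 16.0). The hairpins MIR192 and MIR194-2 are neighbors in MIR194-2HG on chromosome 11 (MIR192 at 64891137 to 64891246, minus strand). miR-194-5p also has a hairpin on chromosome 1, MIR194-1, and its reads cannot be assigned to either place. miR-885-5p had 8 reads against 0, at least 35.6-fold higher (exact lower end 22.8). miR-101-3p was nearly level, at 10950 CPM in HepG2 and 10419 in MHCC97H. The hepatocyte miRNA miR-122-5p had 979 CPM in MHCC97H and 1051 in HepG2, a ratio of 0.93 (0.61 to 1.48). The list's median log2 ratio was -1.93, at the 0.21 percentile. miR-192 and miR-194 also belong to the p53-induced list. That list had 2 of 8 members higher in HepG2 and 1, miR-107, higher in MHCC97H (3.85-fold, 1.63 to 11.97). Its median of -0.66 lay at the 6.26 percentile, while its mean was 0.31.

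By log2 ratio with the 1 CPM pseudocount, the 8 largest HepG2 excesses among miRNAs at 100 CPM or more were miR-6750-5p, miR-483-5p, miR-885-5p, miR-483-3p, miR-146a-5p, miR-551a, miR-200a-5p and miR-429. miR-6750-5p had 717 reads against 0, at least 3187-fold higher (exact lower end 2585). Its hairpin lies in an intron of ATG2A on chromosome 11 (64898363 to 64898437, minus strand). miR-483-5p had 124 reads against 0, at least 551-fold higher (exact lower end 442), and miR-483-3p had 5 against 0. Both arms come from an intron of IGF2 (chromosome 11, 2134134 to 2134209, minus strand). The neighboring imprinted transcript H19 carries miR-675, which went the other way. miR-675-5p had 120 reads in MHCC97H and miR-675-3p had 116, each with none in HepG2. They were at least 3.00-fold and 2.90-fold higher (exact lower ends 2.40 and 2.32). The list of these 4 arms had a median log2 ratio of 0.40, at the 57.0th percentile, with a mean of -0.75 and a negative median under both forms of median centring. miR-146a-5p, a regulator of inflammatory signaling, was 85.3-fold higher in HepG2 (53.02 to 144), with 128 reads against 20. miR-551a was 80.0-fold higher (9.71 to 3680), on 6 reads against 1.

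The miR-200 family, which maintains the epithelial state, split by genomic cluster. All 4 members of the chromosome 1 cluster at 10 CPM or more were higher in HepG2 beyond counting error. miR-200b-3p was 5.25-fold (3.49 to 7.75), miR-200a-3p 24.2-fold (11.1 to 56.0) and miR-200a-5p 50.0-fold higher (15.9 to 207). miR-429 was 53.3-fold higher (5.28 to 2627) on 4 reads against 1. The chromosome 12 cluster was higher in MHCC97H for miR-200c-3p (12.8-fold, 6.74 to 28.1) and miR-141-5p (54 reads against 0, at least 1.35-fold, exact lower end 1.06). miR-141-3p (213 CPM against 87.6) and miR-200c-5p (14 reads against 0) did not pass the counting criterion. MIR200B starts at 1167104 on chromosome 1 and MIR200C at 6963699 on chromosome 12. The family's median of -0.56 lay at the 12.1 percentile, with a mean of 0.02. It was 1.28 without the filter on low values, and -1.94 with zeros at 3 reads, at the 0.36 percentile, where miR-200c-5p falls on the HepG2 side by construction.

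**Figure D2:**
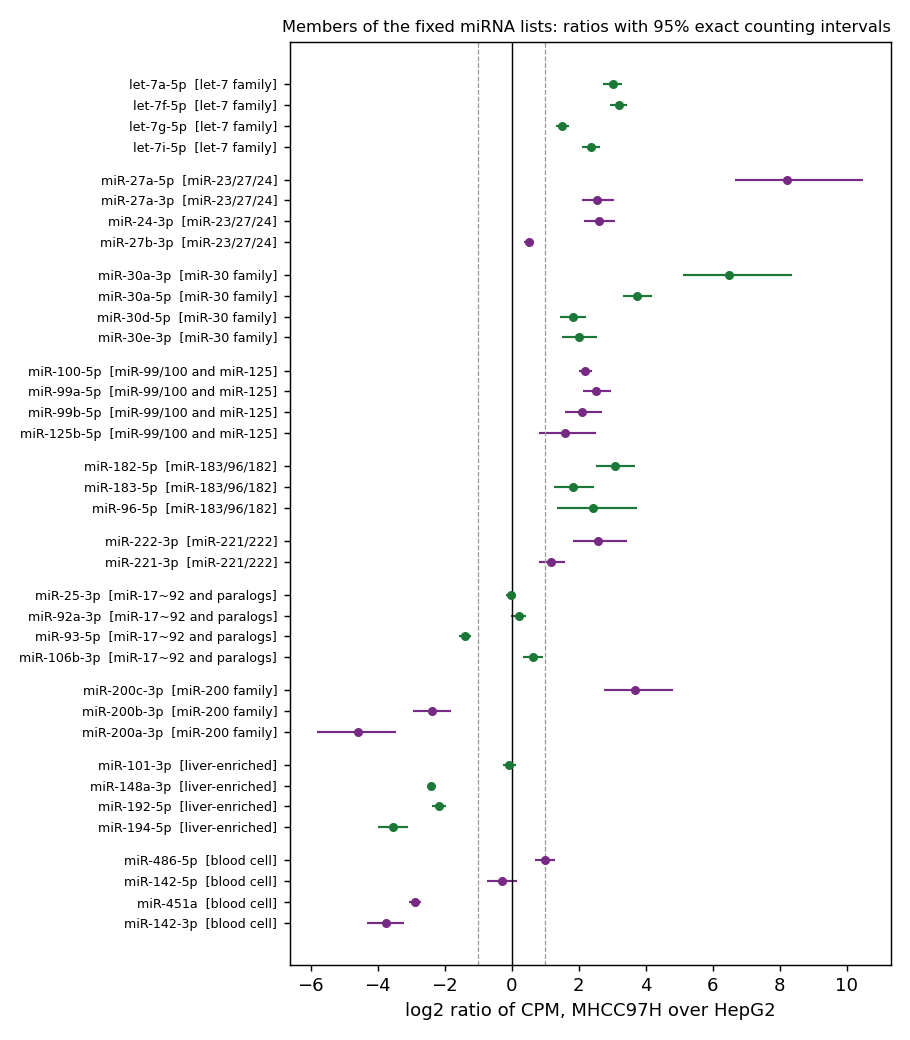
Log2 ratio of CPM in MHCC97H over HepG2 (x axis) for the most abundant members of 10 fixed lists that were detected in both libraries (y axis); points are ratios, bars are 95% exact counting intervals, and dashed lines mark 2-fold. All 4 let-7 members shown lie beyond 2-fold on the MHCC97H side, and miR-148a-3p, miR-192-5p and miR-194-5p lie beyond it on the HepG2 side.

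The miR-17~92 clusters and the miR-29 family had few members that met both criteria. In the miR-17~92 cluster and its paralogs, which drive proliferation, 2 of 21 members were higher in MHCC97H and 1 in HepG2. miR-25-3p (0.98-fold, 0.88 to 1.09) and miR-92a-3p (1.15-fold, 0.99 to 1.35) were level within counting error, miR-106b-3p was 1.55-fold higher in MHCC97H (1.27 to 1.91), under the size criterion. miR-93-5p was 2.64-fold higher in HepG2 (2.33 to 3.00). The median of 0.93 lay at the 59.1st percentile, and was below 0 with median centring. With zeros at 3 reads it was 0.67, at the 97.9 percentile. In the miR-29 family, miR-29a-3p had a ratio of 1.11 (0.86 to 1.45) and miR-29b-3p of 1.41 (0.89 to 2.37). Of 7 members, 1 passed: miR-29c-3p, 6.67-fold higher in HepG2 (1.08 to 31.2) on 3 reads against 6. The family's median of 0.57, at the 16.9th percentile, also changed sign with centring. The imprinted 14q32 cluster leaned to HepG2, with 6 of 42 members higher there, none in MHCC97H and 36 that did not meet both criteria. miR-493-5p was 3.93-fold (2.77 to 5.49) and miR-493-3p 2.01-fold higher in HepG2 (1.17 to 3.27), while miR-379-5p (0.84, 0.65 to 1.10) and miR-381-3p (0.93, 0.71 to 1.24) were level within counting error. Its median of -0.65 lay at the 0.19 percentile, with a mean of 0.07. The C19MC cluster, the Xq27 cluster and the stem cell clusters were barely present. miR-302a-5p, with 3 reads in each library, was the most abundant in those 3 lists. The 3 stem cell entries at 10 CPM or more had a median of -3.61, at the 1.92 percentile, on no more than 3 reads each. All 3 passed the 10 CPM filter only through HepG2, where 1 read is 43.8 CPM. Their HepG2 direction was thus set by the filter, and the percentile says nothing of the cell lines.

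Markers of other cell types were present in both libraries. The red cell miRNAs miR-451a and miR-486-5p had 20104 and 4205 CPM in HepG2, and 2716 and 8313 CPM in MHCC97H. miR-451a was thus 7.40-fold higher in HepG2 (6.59 to 8.31), and miR-486-5p 1.98-fold higher in MHCC97H (1.61 to 2.45), just under the size criterion. The leukocyte miRNA miR-142-3p was 13.6-fold higher in HepG2 (9.28 to 19.8), while miR-142-5p was level (0.81, 0.60 to 1.13). Of 11 blood cell members, 2 were higher in HepG2 and none in MHCC97H by both criteria, and 9 did not meet both. Their median was 0.19 at the 21.8th percentile, which changed sign under 4 settings, and their mean was -0.07. The mesenchymal list had 2 of 11 higher in HepG2, a median of -0.59 and the 11.6th percentile. Its most abundant member, miR-143-3p, had 18167 CPM in MHCC97H and 20849 in HepG2, and miR-199b-5p was 2.30-fold higher in HepG2 (1.56 to 3.30). The endothelial miR-126-3p was level (1.04, 0.87 to 1.24), and miR-126-5p was 5.78-fold higher in HepG2 (3.50 to 9.30). Of 5 muscle members, 2 were higher in MHCC97H: miR-1-3p (11.3-fold, 5.92 to 24.7) and miR-206 (228 reads against 0, at least 5.70-fold, exact lower end 4.60). The neural list had 3 of 7 members higher in MHCC97H, among them miR-128-3p (2.22-fold, 1.23 to 4.50). It had 2 higher in HepG2, among them miR-9-5p at 3.14-fold (1.52 to 5.97). The neural and muscle medians, 4.77 and 5.08, lay at the 58.9th and 91.2nd percentiles, and rested on members with no HepG2 read, so that their direction stays open.

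Entries that overlap other RNA classes took 11.2% of HepG2 reads (10.8 to 11.7%) and 2.08% of MHCC97H reads (2.03 to 2.13%). Without miR-1246 the shares were 1.28% (1.14 to 1.44%) and 0.839% (0.806 to 0.872%). miR-1246, whose sequence matches part of the U2 small nuclear RNA, was 7.998-fold higher in HepG2 (7.59 to 8.43), and miR-1290 was 9.03-fold higher (7.56 to 10.8). miR-1260b was 2.54-fold higher in MHCC97H (1.81 to 3.69), and miR-1260a 1.99-fold higher (1.39 to 2.95). Of the 10 such entries, 2 were higher in each library by both criteria. Their median of -0.95, at the 8.15 percentile, was 0.99 among entries at 100 CPM or more. Of 17 members of the vesicle-associated list, 7 were higher in HepG2, 1 (miR-423-3p) in MHCC97H and 9 did not meet both criteria. miR-320b, miR-320c and miR-320d were among the 7. The list's median was -1.17, at the 0.015 percentile, and it shares miR-1246, miR-1290 and some of the blood cell miRNAs with the lists above. In all, 8 of the 23 lists with 3 or more members lay outside the central 95% of random lists, where lists of unrelated miRNAs would give 1.15. The stem cell list, whose direction the 10 CPM filter set, is among these 8. Lists share members, so these are not independent. Members of 1 list can also be arms of the same hairpin or similar sequences. The random lists do not copy this, so 1.15 is not an exact expectation.

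Of the miRNAs detected in 1 library, 431 were listed in MHCC97H and 30 in HepG2. Of the 431, 48 exceeded the 131 CPM that a count of 0 allows in HepG2. For the rest, a difference was not detectable at this depth. By log2 ratio with the 1 CPM pseudocount, the 8 largest in MHCC97H were all among these 48, although their bounds lie below the folds of miR-27a-5p and miR-30a-3p. They were miR-16-2-3p (919 reads, at least 23.0-fold), miR-24-2-5p (830, 20.7-fold), miR-27b-5p (685, 17.1-fold), miR-30c-2-3p (630, 15.7-fold), miR-98-5p, let-7b-3p (456, 11.4-fold), miR-125b-1-3p (448, 11.2-fold) and miR-181a-3p (426, 10.6-fold). Their exact lower ends ran from 8.62 to 18.6. Apart from miR-98-5p, each is the star arm of its hairpin, the arm usually discarded.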

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

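The 500 CPM mean, the interval rule, thinning, the sum of repeated entries, centring over 500 CPM and zeros at 3 counts were chosen after seeing the data. The filter of 10 CPM and the pseudocount of 1 CPM both lie under 1 HepG2 read, which limits every count by size. TMM scaling (276 for MHCC97H, 139 for HepG2), both pseudocounts, the 4-fold threshold (232 and 92) and summed entries (276 and 144) left both counts within 1.5 times of 281 and 137. Where a value moved, the cause was not tested unless the construction gives it. The counts were 531 for MHCC97H with no filter, 154 and 54 at 100 CPM, 184 for MHCC97H with arms summed, and 68 and 25 at a mean of 500 CPM. They were 111 and 49 with the interval. With zeros at 3 reads they were 125 and 186, but 109 of the 186 had no HepG2 read and were set to that side by the floor, so this setting says nothing of the balance. The 431 miRNAs listed in MHCC97H alone became 181 at 10 CPM, 48 above the HepG2 floor and 145 after thinning. Thinning raised the 30 listed in HepG2 alone to 95. Without entries overlapping other RNA classes, the 10 most abundant took 47.8% and 66.9% of reads. Pearson's r was 0.67 with no filter, 0.41 at 100 CPM, 0.37 and 0.65 with pseudocounts of 0.1 and 10, and 0.18 at a mean of 500 CPM, where rho was 0.37. Lists outside the central 95% numbered 3 at a mean of 500 CPM.

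Several list medians changed sign. With median centring they were -0.19 for miR-17~92 and paralogs, -0.74 for the HCC-reduced list, -0.92 for blood cell miRNAs, -0.54 for miR-29, and -0.72 for IGF2 and H19. Centring over 500 CPM gave -0.062, -0.61, -0.80, -0.42 and -0.59. A total without the 10 most abundant gave -0.28 for the HCC-reduced list, -0.47 for blood and -0.080 for miR-29. No filter gave 1.28 for miR-200. A filter of 100 CPM gave -0.10 for the HCC-reduced list and 0.99 for other RNA classes, arms summed gave -0.10 for the HCC-reduced list, and a mean of 500 CPM gave -0.30 for blood. Zeros at 3 reads gave -0.47 (HCC-reduced), -0.093 (neural), -0.51 (muscle), -0.46 (miR-29), -1.41 (IGF2 and H19) and 0.22 (other RNA classes), which are bounds whose signs the floor can set. No paired analysis was possible because there was 1 library per cell line, and leaving out replicates was not applicable for the same reason.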

Other observations

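All tests in this part were chosen after the results were seen. By share of reads, let-7 miRNAs made up 16.9% of the MHCC97H library (95% exact interval 16.7 to 17.0%) and 2.74% of the HepG2 library (2.53 to 2.96%). The miR-23/27/24 clusters took 10.1% (9.96 to 10.2%) and 3.05% (2.83 to 3.28%), and the miR-30 family 6.63% (6.54 to 6.72%) and 1.26% (1.12 to 1.41%). Without miR-27a-5p the miR-23/27/24 shares were 6.15% and 3.04%, and without miR-30a-5p the miR-30 shares were 3.94% and 1.06%. Liver-enriched miRNAs took 4.27% (4.20 to 4.34%) and 17.1% (16.6 to 17.5%), most of it miR-148a-3p, without which the shares were 1.57% (1.53 to 1.62%) and 2.81% (2.60 to 3.03%). MIR6750, the hairpin of the HepG2 entry miR-6750-5p, lies on the strand of MIR192 and MIR194-2 on chromosome 11, starting at 64898363 against 64891137 and 64891355.

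HepG2 exosomes carried a lower pooled share of the minor arm over 72 families with at least 20 reads in each library. The minor arm is here the strand with the lower share averaged over both libraries. For hairpins with several copies, an arm with 1 shared name was counted at its highest entry, while partner arms named per copy were summed. This can raise the share of the arm named per copy, and the sum of repeats was not run here. The minor arm was still over 50% in MHCC97H for 4 families (miR-27a, miR-16, miR-181a and miR-135b) and in HepG2 for 2 (miR-142 and miR-30e). Its share was 11.6% of 259865 reads in MHCC97H and 2.03% of 17779 in HepG2. Without miR-27a it was 7.50% and 2.02%, and in the 66 families with the same minor arm in both libraries 6.68% and 1.42%. Over all 72, it was lower in HepG2 for 55 families and higher for 17, with intervals apart in 20 and 4. Draws with the MHCC97H split gave a median of 41 lower, an upper end of the central 95% of 49 and a highest of 59, so 55 passed the central 95% but not the highest draw. miR-21-3p made up 5.58% of miR-21 reads in MHCC97H (5.37 to 5.79%) and 0.508% in HepG2 (0.354 to 0.706%), and miR-148a-5p made up 4.69% of miR-148a reads (4.25 to 5.16%) and 0.307% (0.147 to 0.563%). HepG2 had 361 minor-arm reads where the MHCC97H split gives 1191, a ratio of 0.303 (bootstrap over families 0.161 to 0.681). This ratio holds the HepG2 mix of families fixed, while the pooled shares also differ by that mix. MHCC97H thinned to the HepG2 depth gave 0.969 to 1.04, which argues against sampling noise at that depth. In the 66 families the ratio was 0.247, against 0.945 to 1.06 after thinning. The 5 largest deficits against the MHCC97H split were in miR-21 (349 reads), miR-148a (143), miR-15b (106), miR-16 (96.5) and miR-27b (33.1). Most of the missing minor-arm reads thus lay in these families. A few hairpins carrying the whole deficit, or loss of one side of the hairpin, stay open as candidate explanations. Without the 5 families of largest deficit, 50 of 67 were lower, against a median of 39, an upper end of the central 95% of 46 and a highest of 54 in 10000 draws with the MHCC97H split. It passed the central 95% but not the highest draw, the bound set for that test. With a 5p minor arm 21 of 29 were lower (upper end of the central 95% of draws 21), and with a 3p minor arm 34 of 43 (30). These last 2 explanations were tested in 3 forms, each set after values were seen. The first form, the ratio against the thinned range, argued against both: 0.747 without the 5 families, 0.504 for 5p and 0.209 for 3p. The next, bootstrap bounds, left both open (0.418 to 1.16, 0.183 to 1.23 and 0.0994 to 0.604), as did the count of families. A difference between the cell lines in arm selection, and one between library preparations, were not tested and cannot be told apart with 1 library each.

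With library totals, blood cell miRNAs lay on both sides. Of 10 with at least 20 reads over both libraries, miR-451a and miR-142-3p lay above 1 for HepG2, 1 (miR-486-5p, 1.98-fold) lay above 1 for MHCC97H, and 7 did neither. With median centring the sides were 5 for HepG2 and 0 for MHCC97H. Scaling does not change the ratios between members. Of their 45 pairs, 19 had intervals apart, against a median of 0 and a highest of 11 in 10000 draws with 1 common ratio. The draws hold counting error only, so with 1 library per line the pairs could not decide, whatever their number. A common ratio would also hold only if all reads of these miRNAs came from that source. One blood source adding all its miRNAs alike therefore stays open. A source adding them unevenly was not tested, nor was a biological explanation.

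Entries overlapping other RNA classes also moved apart. Of 7 with at least 20 reads over both libraries, miR-1246 and miR-1290 lay above 1 for HepG2, 3 (miR-1260a, miR-1260b and miR-7977) above 1 for MHCC97H, and 2 did neither. With median centring 3 lay above 1 for HepG2 and none for MHCC97H. Of their 21 pairs, 13 had intervals apart, against a median of 0 and a highest of 10 in the draws. A lower miRNA yield raising all RNA-fragment entries alike stays open for the same reason. The 3 entries with fewer reads were not compared. For both groups 3 forms were run, each set after values were seen. A count of sides left the blood source open, argued against the lower yield, and depended on scaling. A comparison with the 2 members of lowest ratio argued against both explanations, but its direction was fixed by picking those 2, so it was replaced by the pairs. The draws of pairs were first 1000, then 10000 as for the arms, and both were passed; the bound of 1 library was set after that. A source of miR-1246 and miR-1290 alone was not tested, nor was a biological explanation.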
